A study of Rattus norvegicus with 6 samples.

How the data were processed

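The data are 6 RNA sequencing libraries of the rostral ventromedial medulla of rats, 3 after CFA and 3 after saline, each given as 50 µL into the temporomandibular joint on both sides and taken on day 3. Groups and replicate numbers came from the sample titles. Per the labels' protocols, messenger RNA was captured from total RNA on poly-T beads, fragmented, copied with random hexamers, amplified by PCR and sequenced as paired ends on a DNBSEQ-T7 instrument. A protocol that marks the strand is not described there.

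The authors deposited a table of FPKM values, with 1 column per library and 22976 genes under Ensembl identifiers. Per the submitters' processing notes, fastp 0.21.0, HISAT2 2, StringTie 2, DESeq2 1.30.1 and the genome build mRatBN7.2 were used, with no role or order given. The counter, the annotation release and any filter on genes are not given in the sources used here. No gene was at 0 in all 6 libraries. Without a stated strand or rule for shared reads, genes with near-identical copies or overlapping neighbours may hold each other's fragments. No per-sample column was left unused.

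The FPKM of a gene moved in whole steps, so fragments could be worked out. The ratio of the smallest steps between libraries gave relative depth, and the steps over genes gave each gene's length and each library's total. In 22963 genes (99.9%) all 6 values came out as whole fragments within 0.0001, with totals of 27534174 to 44977905 fragments per library. Whether a fragment here is a read or a read pair is not given in the sources used here. Where the fragments of a gene all share a divisor with its length, both are known only up to that divisor. The recovery was tested on 3791 simulated genes. All 6 totals were recovered, and the fragments of 98.6% of genes. Fragments served to give depth, spread and alternatives, and the main test used FPKM.

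Genes with a mean of at least 1 FPKM over the 6 libraries (13566) were tested. The values were log2(FPKM + 1), the pseudocount being 1 FPKM, and limma 3.58.1 in R 4.3.3 was fitted to CFA against saline over all 6 libraries (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested. There were 4 residual degrees of freedom. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Fold changes are on the log2(FPKM + 1) scale. Counts are given at an adjusted p under 0.05 and at an unadjusted p under 0.05 with at least a 2-fold change. Variance over counting noise was computed from fragments in genes with at least 5 expected in each library compared.

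The fit was tested on simulated fragments for 13555 of the genes, with the totals of these libraries, a variance of 3 times counting noise and 50 genes changed in each of 4 ways. Of the genes raised 1.5-fold, 72% were called, and of those lowered 1.5-fold, 62%. At 2-fold the shares were 96% and 84%. Of 13355 unchanged genes, 7 were called, and with no gene changed at all 0 were called. The simulated fit held no variation between animals and no change under 1.5-fold. It therefore does not show false calls from such variation, nor recovery of smaller changes. The spread estimate returned 2.89 to 3.23 times counting noise in simulated genes with a constant factor of 3.

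The tests, thresholds, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Part of that design was not run. It held tests of the C1q, C3 and CR3 genes, of 40 gene lists with camera and fry, and a rule that named the 10 genes with the largest rise and the 10 with the largest fall among those past the adjusted threshold whose groups did not overlap, leaving out identifiers without a symbol. It also named the C1q, C3 and CR3 genes always, up to 4 members of each list described, and markers of other cell types or RNA quality in lists that moved. The files do not pair identifiers with symbols, and 0 of the 22976 identifiers matched the reference table of gene names used here. Those genes, lists, markers of other cell types and of RNA quality are therefore not analysed here. In place of that rule, the 2 identifiers with the largest rise and the 2 with the largest fall among genes past the adjusted threshold whose groups did not overlap are given, a choice made after the files were seen.

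Alternatives covered the pseudocount (0.1 and 0.01), the filter (any value above 0, a mean of at least 0.1 and of at least 5 FPKM), the scaling (median ratio, FPKM rescaled to the same larger sum in each library, as for TPM, quantile), the variance moderation (no trend, robust), the replicate number as a block, each library left out in turn and a log2 threshold of 0.58 in place of a 2-fold change. Added after seeing the data were limma's voom on recovered fragments, cyclic loess scaling, fragments thinned to the depth of the shallowest library and removal of a trend with gene length in each library. The labels give no sequencing batch or date.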

Results

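Gene expression was measured by poly-A RNA sequencing in the rostral ventromedial medulla (RVM) of rats, a brainstem region whose descending projections can raise or lower the transmission of pain signals. The rats had received 50 µL of CFA (complete Freund's adjuvant, an oil emulsion with killed mycobacteria that inflames tissue) or saline into the temporomandibular joint (TMJ, the jaw joint) on both sides, and day 3 was profiled. There were 3 libraries from CFA rats and 3 from saline rats. The table lists 22976 genes, each with an FPKM value (fragments divided by gene length and library total) in all 6 libraries. Library totals worked out from the steps between FPKM values were 44977905, 34440104 and 38212928 fragments for saline replicates 1, 2 and 3 and 38260153, 27534174 and 32305437 for CFA replicates 1, 2 and 3. The 22963 listed genes whose values came out as whole fragments held 98.8% to 98.9% of these fragments, and the other listed genes were not counted. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

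The comparison of CFA with saline asked which transcripts of the RVM differed 3 days after the joint was inflamed, in a study of pruning of synapses by microglia in orofacial pain. Many genes differed, mostly by little, and the large changes were mostly increases. Of 13566 genes with a mean of at least 1 FPKM, 2545 (18.8%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 1530 higher and 1015 lower in CFA. Among these, 187 differed by at least 2-fold on the scale of FPKM + 1, 182 higher and 5 lower. The median log2 change was 0.31 for the genes that rose and -0.16 for those that fell.

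The files pair no gene identifier with a name, so the largest changes are given by identifier. ENSRNOG00000013973 had the largest rise, from 0.562 ± 0.0957 FPKM in saline to 78.2 ± 3.68 FPKM in CFA (SD, n = 3 each), or 75 fragments over the 3 saline libraries and 8662 over the 3 CFA libraries. Its log2 change of FPKM + 1 was 5.66 (SE 0.0566, adjusted p = 1.63e-09, limma with Benjamini-Hochberg adjustment), and the ratio of the group means was 139. ENSRNOG00000002217 rose from 0.471 ± 0.280 to 30.3 ± 3.06 FPKM (SD, n = 3 each), a log2 change of 4.42 (SE 0.131, adjusted p = 3.51e-07, limma). Its saline values rested on 36 fragments, of which 22 were in saline replicate 1.

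The largest fall was that of ENSRNOG00000012067, from 7.89 ± 0.102 FPKM in saline to 0.592 ± 0.115 FPKM in CFA (SD, n = 3 each). Its log2 change was -2.48 (SE 0.0697, adjusted p = 2.61e-07, limma with Benjamini-Hochberg adjustment), and its fragments went from 2266 over the saline libraries to 142 over the CFA libraries. ENSRNOG00000027271 fell from 31.9 ± 6.52 to 6.01 ± 2.49 FPKM (SD, n = 3 each), a log2 change of -2.28 (SE 0.250, adjusted p = 0.00061, limma). Its values ranged from 25.7 to 38.7 FPKM in saline and from 3.63 to 8.60 FPKM in CFA. The 4 identifiers were picked among genes whose groups did not overlap.

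**Figure D1:**
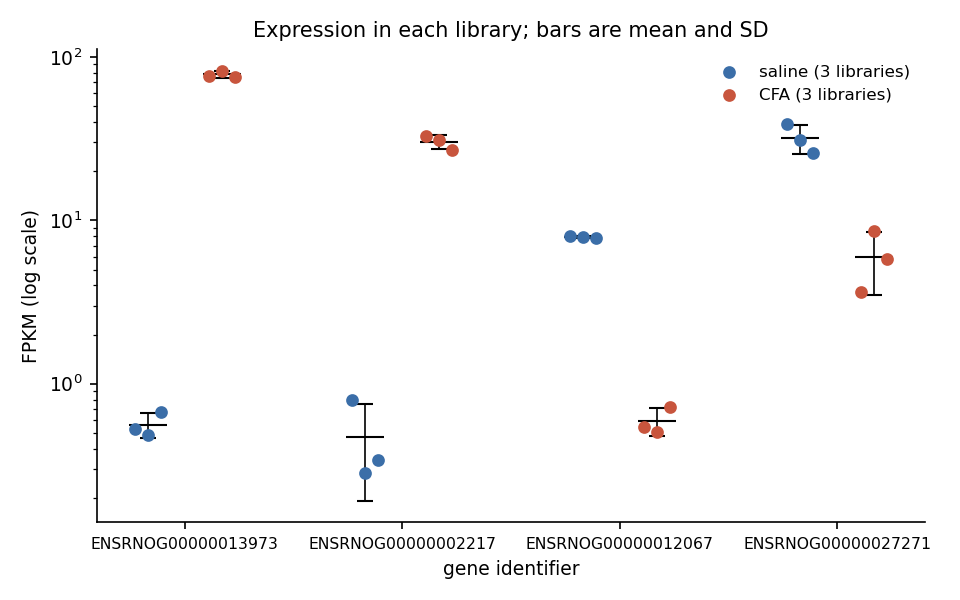
FPKM on a log axis of the 4 identifiers with the largest rises and falls, 1 point per library (3 saline, 3 CFA), with horizontal bars for the group mean and error bars for the SD. The identifiers were picked among genes whose groups did not overlap; ENSRNOG00000013973 went from 0.562 to 78.2 FPKM and ENSRNOG00000012067 from 7.89 to 0.592 FPKM.

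Some of the genes that rose were low in saline. There were 84 genes past the adjusted threshold (limma, Benjamini-Hochberg) with a mean under 1 FPKM in saline and of at least 2 FPKM in CFA, and 1 gene with the reverse, ENSRNOG00000012067. Of the 84 genes, 66 rose at least 2-fold on the scale of FPKM + 1 and 18 rose by less. The 182 genes that rose at least 2-fold held 0.221% ± 0.00339 of all FPKM in saline and 0.765% ± 0.00686 in CFA (SD, n = 3 each). All 1530 genes that rose went from 10.6% ± 0.0204 to 12.8% ± 0.0243 of all FPKM, and the 1015 that fell from 27.1% ± 0.0298 to 25.3% ± 0.0273. These genes were chosen on the same libraries, so their shares describe the lists and do not test them.

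Small changes went both ways. Of the genes past the adjusted threshold (limma, Benjamini-Hochberg), 2135 changed by less than 0.58 on the log2 scale, 1147 higher and 988 lower. Beyond 0.58 there were 383 higher and 27 lower. Of all genes tested, 5115 (37.7%) had groups that did not overlap, where chance gives 10%. The first principal component held 65.2% of the variance and separated the groups. Across genes, which are not independent replicates, the correlation of log2 values was 0.993 to 0.995 between libraries of a group and 0.982 to 0.983 between groups.

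**Figure D2:**
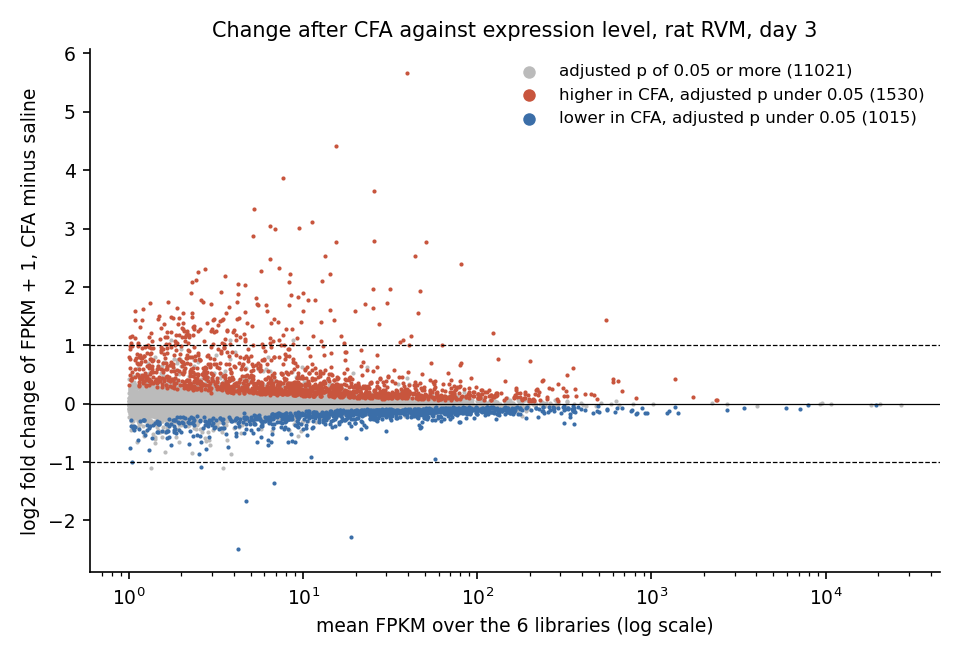
Log2 change of FPKM + 1 from saline to CFA (3 libraries each) against the mean FPKM of each of 13566 genes on a log axis, with dashed lines at a 2-fold change. Red points are the 1530 genes higher and blue points the 1015 genes lower in CFA at an adjusted p under 0.05 (limma, Benjamini-Hochberg); past the dashed lines there were 182 higher and 5 lower.

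The direction of change varied with the expression level, with FPKM scaled as given, by median ratio or to the same sum. With quantile scaling the medians of all classes were negative. With cyclic loess scaling, added after seeing the data, the trend shrank. Among the 1850 genes of 1 to 2 FPKM, 199 passed the adjusted threshold as higher and 58 as lower (limma, Benjamini-Hochberg), and the median gene lay 0.068 higher in CFA on the log2 scale. Among the 926 genes of 50 to 200 FPKM, 151 passed as higher and 278 as lower, and the median gene lay at -0.035. Among the 154 genes of at least 200 FPKM, 43 passed as higher and 66 as lower, with a median of -0.025. The SD of these class medians between libraries of a group was at most 0.0081. On the log2(FPKM + 1) scale the medians at 1 to 2 and at 50 to 200 FPKM were 0.038 and -0.040 as given, and -0.048 and -0.028 with quantile scaling, which gives all libraries the same distribution. With cyclic loess scaling, which removes trends with expression level, they were 0.0062 and -0.018. In the same direction, 13434, 13382 and 13394 genes reached 1 FPKM in saline replicates 1, 2 and 3, and 13678, 13669 and 13623 in CFA replicates 1, 2 and 3.

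**Figure D3:**
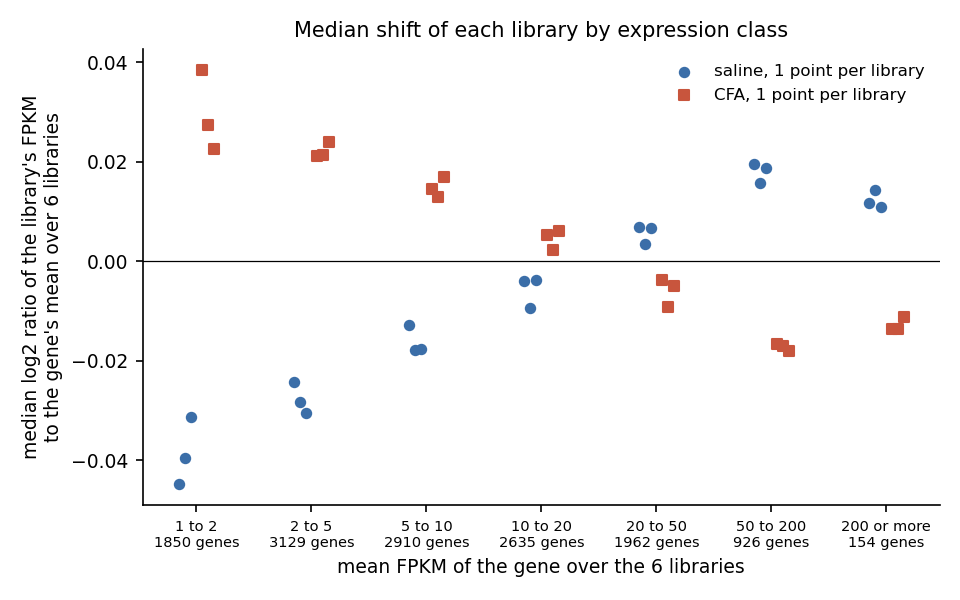
Median log2 ratio of a library's FPKM to the gene's mean over the 6 libraries, by class of mean FPKM, with 1 point per library (blue circles saline, red squares CFA). The CFA libraries lay above the saline libraries in genes of 1 to 2 FPKM (by 0.068) and below them in genes of 50 to 200 FPKM (-0.035); on the log2(FPKM + 1) scale the low class turned to -0.048 with quantile scaling and lay at 0.0062 with cyclic loess.

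Libraries of a group resembled each other closely. The median coefficient of variation of a gene was 4.54% in saline and 4.84% in CFA over 3 libraries each. In fragments, the variance between libraries, as a mean over genes, was 2.88 to 3.11 times counting (Poisson) noise in the 6 pairs of libraries within a group. In the 9 pairs between groups it was 14.7 to 18.3 times. The median over genes, set against the median of counting noise, was 2.80 to 2.92 within groups and 5.71 to 6.30 between groups. Within saline the mean was 2.76 times in genes of 100 to 300 fragments over all libraries and 3.25 times in genes of 30000 to 100000 fragments. In CFA these values were 2.72 and 3.17. In genes above 100000 fragments the means were 6.67 in saline and 4.93 in CFA, and the medians over genes were 4.18 and 3.22. No pair of libraries agreed within counting noise, so none was a plain copy of another, and all 6 were kept. Repeated sequencing of the same library was not excluded.

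**Figure D4:**
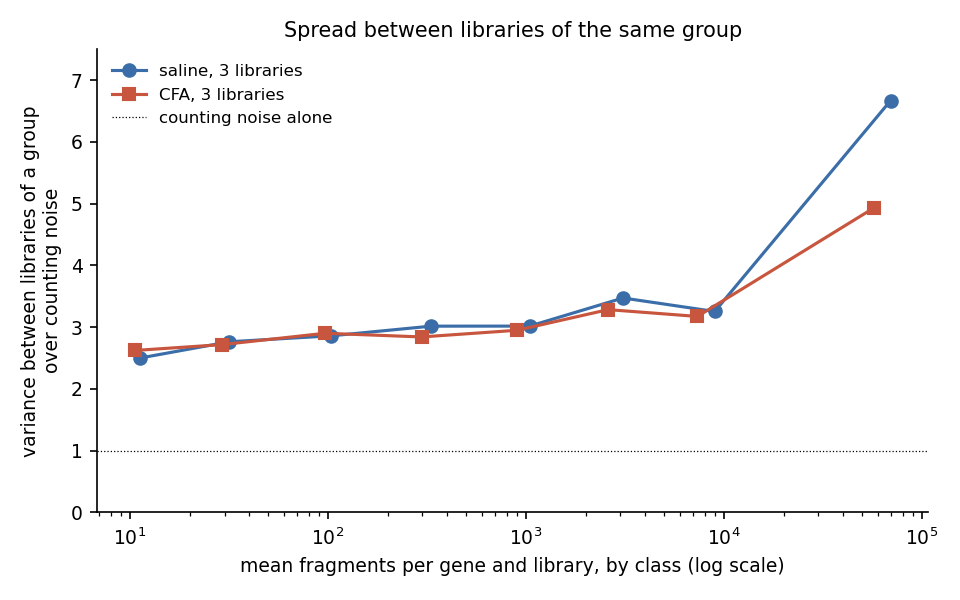
Variance between the 3 libraries of a group over counting noise, against the mean fragments per gene and library on a log axis, by class of fragments (blue circles saline, red squares CFA, dotted line counting noise alone). Points are means over genes. The mean stayed near 3 times counting noise up to 100000 fragments over all libraries. Above that it was 6.67 times in saline and 4.93 times in CFA, with medians over genes of 4.18 and 3.22.

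The test was limma on log2(FPKM + 1), which understates the change of genes with low FPKM. Without false-discovery control, 4395 genes had an unadjusted p under 0.05, and 191 of them differed by at least 2-fold, 184 higher and 7 lower. The balance of rises and falls among all genes past the adjusted threshold varied with the scaling of the libraries. Of these genes, 60.1% were higher with FPKM as given and 46.3% with quantile scaling (1197 higher, 1391 lower). More were higher than lower with median ratio scaling (1398 and 1219) and cyclic loess (1455 and 969). The same held with FPKM rescaled to the same larger sum (1607 and 1030). The balance of small changes alone was not examined under each scaling. The 1015 genes that fell became 598 without saline replicate 1, 636 without saline replicate 3 and 666 with limma's variance moderated without a trend, and the 191 genes became 77 among genes of at least 5 FPKM and 344 with FPKM rescaled to the same larger sum in each library.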

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

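The settings with voom, cyclic loess, equal depth and the length trend removed were chosen after seeing the data. The 4 named identifiers kept their direction and an adjusted p under 0.05 (limma) in all alternatives in which they were tested, 21 each and 20 for ENSRNOG00000012067. They had been picked as the largest changes in these same libraries, so this outcome was likely from the start and is no separate support. The count of 2545 genes at adjusted p under 0.05 lay between 1743 and 3468 over all alternatives, and no gene called both there and in the main setting changed sign. Leaving out each library in turn gave 1743 to 2014 genes, and 598 to 778 lower against 1015. Each such fit had fewer libraries. Without the trend in limma's variance 666 were lower, and the cause was not tested. Quantile scaling gave 1197 higher and 1391 lower.

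The count at unadjusted p under 0.05 and at least 2-fold, 191 (184 higher, 7 lower), was 315 (297 and 18) with a pseudocount of 0.1, 331 (309 and 22) with 0.01, 344 (319 and 25) with FPKM rescaled as for TPM, and 329 (310 and 19) with voom on recovered fragments. A smaller pseudocount widens the folds of low genes by construction. Rescaling as for TPM also let more genes through the filter (15389 tested against 13566), and voom also changed the weights, and what each of these added was not tested. A mean of at least 5 FPKM gave 77 (75 and 2), with 8587 genes tested. A log2 threshold of 0.58 gave 437 (401 and 36).

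With the replicate number as a block, 2086 genes passed the adjusted threshold (limma), 1277 higher and 809 lower. Libraries with the same number did not deviate together (correlations of -0.021 to 0.023 across genes), so no large effect shared by number was seen. A small one could be missed, and the labels do not say what the numbers mark. Saline replicates 2 and 3 correlated best with their own number in these deviations and saline replicate 1 did not. Alternatives not run for want of gene symbols were camera with an estimated correlation, fry, and all alternatives for the C1q, C3 and CR3 genes and the gene lists. The saline values of ENSRNOG00000002217 rest on 36 fragments. Its call held at equal depth (log2 change 4.41 against 4.42), but thinning leaves FPKM unchanged on average and cannot test that limit.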

Other observations

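The tests in this part were chosen after the results they bear on had been seen, except quantile scaling, which was planned, and the tests at equal depth, which were added after the data were seen but had their bounds set before they were run.

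Chance in the grouping was examined by splitting the 6 libraries into 3 and 3 in all 10 ways. The real grouping called 2545 genes at adjusted p under 0.05 (limma, Benjamini-Hochberg), and the highest other split called 1. At unadjusted p under 0.05 and at least 2-fold it gave 191 genes, and the highest other split 9. The 10 splits are too few for a share under 0.05. Every other split also mixes CFA and saline libraries on both sides, so the difference between CFA and saline adds to the spread and lowers the calls. The other splits therefore do not show how many genes chance alone would call.

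Replicate libraries differed by a nearly constant multiple of counting noise. Variation between animals in proportion to expression would raise that multiple in saline from 2.76 in genes of 100 to 300 fragments to 499.7 in genes of 30000 to 100000, but the ratio between these classes was 1.18, which leaves room for a coefficient of variation of 0.739% in the abundant class. The smallest variance among the 6 pairs, 2.88 times counting noise, argues against plain copies of a library, which would not differ at all. The same library sequenced again would give about 1 only if each fragment were an independent draw. Whether a fragment is a read or a read pair is not given, so repeated sequencing of the same library stays open. Simulated animals that varied by 15% gave 194.9 times counting noise in genes of 30000 to 100000 fragments. The saline libraries gave 3.25, which argues against variation of that size. Libraries made from the same RNA or pool within a group would make the p-values cover technical spread. They cannot be told apart from animals that differed very little. The ratio of 1.17 in CFA is the constant multiple itself and no separate test of a pool. The source of the multiple stays open too, and the larger means above 100000 fragments (6.67 in saline and 4.93 in CFA) go beyond it. The medians over genes there were 4.18 in saline and 3.22 in CFA, against 3.27 and 3.19 in genes of 30000 to 100000 fragments. In CFA the typical gene thus stayed near the multiple.

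Genes changed at least 2-fold mostly rose, 184 of 191 at unadjusted p under 0.05 (96.3%). The share higher was 95.1% with quantile scaling and 95.8% with all libraries thinned to the same depth. It was 95.7% with the trend with gene length removed, so neither scaling nor gene length accounts for it alone. These settings had little room to change the share. The median ratio factors of the libraries were 0.995 to 1.007, and the median log2 changes of length classes were -0.0075 to 0.048. Thinning by construction leaves the FPKM of a gene unchanged on average, so the share at equal depth bears only on unequal counting noise. An effect of CFA and RNA of other cells or neighbouring tissue taken with the dissection stay open and untested, the latter because no marker gene was matched.

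Genes of low abundance shifted up in CFA and abundant genes down. The gap between genes of 1 to 2 and of 50 to 200 FPKM, CFA minus saline, was 0.103 on the log2 scale over all genes, against an SD between libraries of a group of at most 0.0074. The gap was 0.127 among genes of 2000 to 4000 bp, so gene length does not account for it alone. At equal depth it was 0.104. Thinning by construction leaves the FPKM of a gene unchanged on average, so that value bears only on unequal counting noise. Other effects of depth were not tested. A few genes taking most of the fragments would move all classes alike and leave no gap. The gap of 0.103, beyond the SD of at most 0.0074, argues against that explanation. Quantile scaling, which removes differences between the distributions by construction, turned the median of the low class to -0.048 on the log2(FPKM + 1) scale, below the -0.028 at 50 to 200 FPKM. Cyclic loess, which removes trends with expression level, left 0.0062 in the low class and -0.018 at 50 to 200 FPKM. The pattern stayed with median ratio scaling (0.030 and -0.053) and with FPKM rescaled to the same larger sum (0.049 and -0.042). It was thus reversed between these classes with quantile scaling and reduced with cyclic loess. Both act on such patterns by construction, so they cannot tell its cause. An effect of CFA, a different mix of tissue and RNA quality stay open and were not tested.

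Some genes varied between libraries beyond the common multiple of counting noise. At a Benjamini-Hochberg adjusted p under 0.05 (chi-square over 3 libraries) there were 28 in saline and 18 in CFA, of 17517 and 17399 genes. The lists shared 12 genes, where lists independent within classes of fragments would share 0.155. Of the 206 genes above 100000 fragments, 7 and 4 were listed.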
